A study of Chlamydomonas reinhardtii with 8 samples.

How the data were processed

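RNA of vegetative cells, grown in TAP medium (which holds acetate) in the light, was sequenced in 8 libraries of 4 groups, made with a NEBNext kit. The groups were WT and dnmt1 in mt+ (CC-5155 strains) and in mt- (CC-5325 strains), with 2 biological replicates each, as the sample titles state. Per the labels, the authors used Trim Galore 2.6, STAR 2.7.6, Picard, featureCounts and DESeq2, with no role or order given. The deposited table of raw counts per gene was the starting point. The authors also deposited a table of normalized signal, which equals the raw counts divided by 1 size factor per library (0.749 to 1.42); the factors recomputed with DESeq2 were the same, and this table was used for that check alone.

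Gene IDs carry the suffix of the CC-4532 v6.1 annotation, which is left off here. The reference table at hand gives v5.5 loci without symbols, so no coordinates are printed, and 15386 of 17693 genes (87.0%) matched it by ID. None of the 2195 nuclear IDs whose number begins with 8 did. Symbols come from a list of loci and symbols written by hand from the standard nomenclature before the data were examined; no file used here pairs them, so each symbol is printed with its locus ID. The gene lists, the comparisons, the tests, the rule for named genes and most alternatives were also fixed before the data were examined. The lists were the antenna, photosystem and Rubisco subunits, the low-CO2 response, iron and copper nutrition, heat shock and chaperones, nitrogen assimilation, mating and gamete genes, DNA methylation, chloroplast-encoded and mitochondrion-encoded genes, and the mating-type region, taken as IDs Cre06.g250650 to Cre06.g255450. Another 8 lists, defined by product names, had no members in the reference table and were not run. The lists of nitrogen assimilation (2 tested members), mating and gamete genes (1) and DNA methylation (1) had too few tested members for a set test.

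Genes were kept by edgeR's filterByExpr on the 4 groups, which left 15263; 572 had no read in any library. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit, 1 mean per group, 4 residual degrees of freedom), and each contrast was tested with glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. It restates the test statistic, and for a gene with few reads in a group it can be smaller than counting error alone. The contrasts were genotype in mt+, genotype in mt-, their difference, their mean, and mating type in WT and in dnmt1. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and beside it camera with an estimated correlation and fry, each adjusted over the 8 lists of a comparison. No list call in any of the 6 comparisons held with an estimated correlation. Chromosomes were tested in the same way, and neighbouring calls against 1000 random placements of the same number of calls with seed 1. Other tools were DESeq2 1.42.0, R 4.3.3, Python 3.11.15 and matplotlib 3.10.9.

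Named genes were those with an adjusted p under 0.05, a mean of at least 5 CPM over the 8 libraries and no overlap between the libraries compared (not asked of the difference), ranked by log2 fold change; the first few each way are printed, since the rest have no symbol here. The examples of a list are its 4 members with the smallest p; members beyond these were named after their values were seen, where a count of 5 or fewer is given in full. The DNMT1 locus and FUS1 were always named. A gene with 0 reads in a group is given as a bound, against a floor of 3 counts per library (0.133 to 0.255 CPM). Bounds cover at most the counting error of the group with 0 reads, as the other group enters by its plain mean. Reads without molecular identifiers are also not independent molecules. Of counts from 2 to 19, 25.5% to 30.8% per library were odd numbers, a pattern that arises where both mates of a pair are counted, so the number of fragments behind a low count may be smaller than the count.

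Data were simulated with 1 spread per gene for all 4 groups, estimated from these libraries, and with 200 changed genes. There, 40.3% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 92.4% of those changed 4-fold were called in mt+. False calls were 3 among 143. The real WT mt+ replicates stood farther apart than the other pairs, so these shares may not carry over to the real mt+ comparison. The alternatives were DESeq2's test, its size factors (RLE) in edgeR, library size scaling, no low-count filter (at least 1 read), a mean of at least 10 CPM, a 2-fold minimum, the 2 compared groups alone, an additive model, the replicate number as a block, and leaving out each library in turn, where the lone library left is assumed to vary like the other groups. Halving the counts was added after the data were seen. A replicate number is shared between groups, but no label says that it marks a batch, so it is in no model but that alternative. The top 50 genes took 15.7% to 19.5% of counts, chloroplast genes 0.0298% to 0.0660% and mitochondrial genes 0.00221% to 0.00388%. At such shares, counts of organelle genes may follow how much of that RNA entered a library, which was not tested.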

Results

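Messenger RNA of vegetative cells of the single-celled green alga Chlamydomonas reinhardtii was measured by RNA-seq in 8 libraries. The alga is haploid and has 2 mating types, mt+ and mt-, set by a region of chromosome 6. Wild type (WT) and strains that the labels call dnmt1, with a DNMT1 knockout, were sequenced in both mating types, which gave 4 groups of 2 biological replicates. DNMT1 is a DNA cytosine methyltransferase. The mt+ groups were of the strain CC-5155 and the mt- groups of CC-5325, so mating type and strain were the same contrast. Library totals ran from 12204374 to 21115955 counts, and 15263 of 17693 genes had enough counts to be tested. Pearson's r of log2 CPM across genes (which are not independent replicates) was 0.980 between the WT mt+ replicates and 0.991, 0.990 and 0.989 in the WT mt-, dnmt1 mt+ and dnmt1 mt- pairs. The WT mt+ replicates stood farthest apart, with an SD of their log2 differences of 0.47 against 0.32 to 0.34 in the other pairs. In what follows, a log2 fold change is given ± its standard error, and a level in CPM (counts scaled by library total and TMM factor) is a mean ± SD with n = 2. That standard error is derived from the test, and for genes with few reads in a group it can be smaller than counting error alone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test.

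The gene listed for DNMT1 before the data were examined, DMT1 (Cre10.g461750), was lower than in WT in the mt+ libraries labelled dnmt1 and higher in the mt- ones. Its level was 28.3 ± 0.0849 CPM in WT mt+ and 14.6 ± 1.97 CPM in the libraries labelled dnmt1 mt+, a log2 fold change of -0.95 ± 0.13 (edgeR, Benjamini-Hochberg adjusted p = 7.78e-05). In WT mt- it was 26.6 ± 3.02 CPM, and in the libraries labelled dnmt1 mt- 87.5 ± 4.99 CPM, a log2 fold change of 1.71 ± 0.11 (edgeR, Benjamini-Hochberg adjusted p = 5.74e-08). The raw counts were 332 and 480 in WT mt+, 648 and 363 in WT mt-, 268 and 197 in dnmt1 mt+, and 1321 and 1337 in dnmt1 mt-. The rise in mt- goes against the direction a knockout label would give. The labels name neither the locus nor the lesion, and a count over a whole gene does not show whether its product is made. These groups are therefore called "libraries labelled dnmt1", dnmt1 in the name of a group or library is that label alone, and each direction below rests on the labels.

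**Figure D1:**
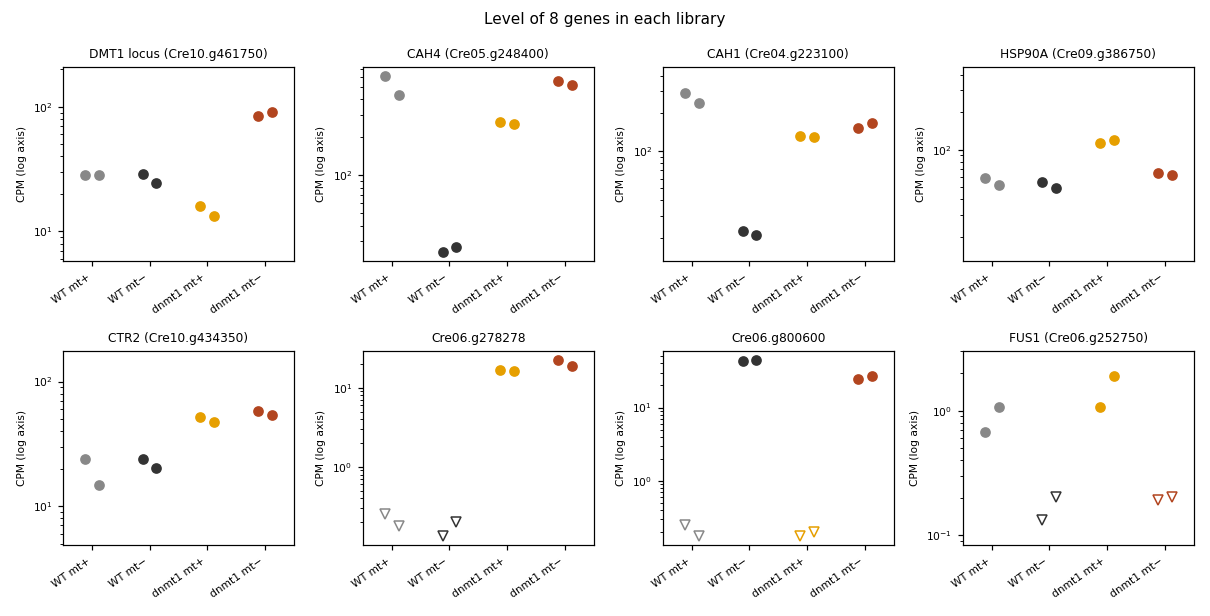
Level of 8 genes in each of the 8 libraries, in CPM on a log axis that differs between panels; each filled point is a library, and an open triangle marks a library with 0 reads, drawn at the level of 3 counts. CAH4 was lowest in both WT mt- libraries, and Cre06.g278278 had 0 reads in all 4 WT libraries and 16.3 ± 0.318 CPM (SD, n = 2) in the libraries labelled dnmt1 mt+.

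The difference between the libraries labelled dnmt1 and WT was asked first in mt+. Chaperone genes were higher in the libraries labelled dnmt1 mt+ than in WT mt+: of 8 tested members of the heat shock list, 7 rose and 1 fell. HSP90A (Cre09.g386750), a cytosolic chaperone, went from 55.8 ± 4.51 to 117 ± 4.60 CPM (log2 fold change 1.07 ± 0.09), and HSP70B (Cre06.g250100), a chloroplast chaperone, from 37.5 ± 7.78 to 71.6 ± 0.692 CPM (0.94 ± 0.11). HSP22E (Cre14.g617450), a small heat shock protein, and HSP70A (Cre08.g372100) rose by log2 fold changes of 0.64 ± 0.12 and 0.42 ± 0.08, while HSP22A (Cre07.g318800) fell by 1.04 ± 0.24 on the log2 scale. The list stood apart from other genes by camera (adjusted p = 0.00380), but not with an estimated correlation (adjusted p = 0.654).

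In the same comparison, of 11 tested members of the iron and copper list, 6 rose and 1 fell (7 and 1 adjusted over the list alone). The copper transporter genes CTR2 (Cre10.g434350) and CTR1 (Cre13.g570600) had log2 fold changes of 1.39 ± 0.16 and 0.86 ± 0.10, the iron-assimilation gene FEA2 (Cre12.g546600) 0.91 ± 0.13, and the ferroxidase gene FOX1 (Cre09.g393150) 0.64 ± 0.09. The member that fell was CYC6 (Cre16.g651050), for cytochrome c6, a marker of copper deficiency (-0.95 ± 0.18). Camera gave an adjusted p of 0.0148 and, with an estimated correlation, an adjusted p of 0.679. The first p was 0.0843 without WT mt+ replicate 2 and 0.0553 without dnmt1 mt+ replicate 1.

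Of the 4 carbonic anhydrase genes on the low-CO2 list, CAH1, CAH4 and CAH5 were lower and CAH3 was higher in the libraries labelled dnmt1 mt+; carbonic anhydrases were not tested as a group. CAH1 (Cre04.g223100), the periplasmic enzyme, fell from 266 ± 35.5 to 131 ± 2.80 CPM (log2 fold change -1.02 ± 0.10). The mitochondrial enzymes' genes CAH4 (Cre05.g248400) and CAH5 (Cre05.g248450) had log2 fold changes of -1.01 ± 0.12 and -1.19 ± 0.12. They are near-identical copies, so reads may be split between them. EPYC1 (Cre10.g436550), for the pyrenoid linker protein, and CIA5 (Cre02.g096300), for a regulator of carbon concentration, also fell (-0.60 ± 0.13 and -0.42 ± 0.10), and CAH3 (Cre09.g415700) and BST3 (Cre16.g663450) rose (0.56 ± 0.10 and 0.63 ± 0.12). With 2 members up and 5 down of 17, the list as a whole did not stand apart (camera adjusted p = 0.413). Among 24 tested antenna genes, LHCBM9 (Cre06.g284200) rose from 26.9 ± 8.86 to 72.2 ± 7.44 CPM (1.45 ± 0.15), and LHCBM4 (Cre06.g283950) and LHCBM8 (Cre06.g284250), similar in sequence, fell (-0.51 ± 0.11 and -0.51 ± 0.12). Of 17 photosystem and Rubisco genes, 1 rose, PSBX (Cre02.g082750) (0.34 ± 0.09). Neither list passed camera (adjusted p = 0.726 for both). Of 67 tested chloroplast-encoded genes 3 were higher and 4 lower, with a median log2 fold change of 0.14 (camera adjusted p = 0.726); the median was 0.62 (adjusted p = 0.00102) without WT mt+ replicate 1 and -0.40 (adjusted p = 0.0248) without replicate 2. The 8 mitochondrion-encoded genes had a median of -0.01 (camera adjusted p = 0.726). The calls of PSBX, CIA5 and LHCBM8 were lost without either library of dnmt1 mt+, that of LHCBM8 also in a fit to these 2 groups alone (edgeR, Benjamini-Hochberg adjusted p = 0.0501), that of HSP22A without replicate 1, and those of LHCBM4 and EPYC1 without replicate 2 of that group.

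Over all tested genes, 1415 were higher and 1348 lower in the libraries labelled dnmt1 mt+, and 410 and 154 of these differed at least 2-fold. Among genes with a mean of at least 5 CPM over the 8 libraries and no overlap between the libraries compared, the largest rises from a level above 0 reads were of Cre06.g800688, from 0.144 ± 0.0367 to 59.1 ± 4.23 CPM (log2 fold change 8.65 ± 0.27), and Cre05.g800549 (6.67 ± 0.19), which have no symbol in the tables used here. Cre05.g800547 and Cre06.g278278, whose place in this order is not known, had 0 reads in both WT mt+ libraries and 17.3 ± 0.125 and 16.3 ± 0.318 CPM in the libraries labelled dnmt1 mt+, at least 80.1-fold and 75.4-fold higher against a floor of 3 counts per library. Cre06.g800688 had 2 reads in each WT mt+ library, below that floor, so the size of its fold change is uncertain. By the same rule the largest falls were of Cre01.g009101, from 17.7 ± 1.60 to 1.81 ± 0.477 CPM (log2 fold change -3.27 ± 0.24), and of Cre16.g686285 (-2.77 ± 0.28). The counts moved with single libraries: 771 higher and 534 lower without dnmt1 mt+ replicate 1, 808 higher and 529 lower without replicate 2, and 1986 higher and 2195 lower without WT mt+ replicate 2. A fit to these 2 groups alone called 814 higher and 705 lower.

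The same question in mt- showed 3 genes of the low-CO2 list, CAH1, CAH4 and CAH5, higher in the libraries labelled dnmt1, while CAH3 (Cre09.g415700) was not called (log2 fold change -0.01 ± 0.09). CAH4 (Cre05.g248400) went from 25.9 ± 1.73 CPM in WT mt- to 540.0 ± 29.0 CPM (log2 fold change 4.39 ± 0.14, edgeR, Benjamini-Hochberg adjusted p = 1.51e-11), CAH5 (Cre05.g248450) from 11.6 ± 1.23 to 200.2 ± 13.1 CPM (4.12 ± 0.14), and CAH1 (Cre04.g223100) from 21.8 ± 1.15 to 161 ± 11.3 CPM (2.88 ± 0.11). The bicarbonate transporter gene LCIA (Cre06.g309000), named with LCID and CCP2 after their values were seen, rose at low level, from 0.112 ± 0.0326 to 1.63 ± 0.572 CPM, and BST3 (Cre16.g663450) rose by 0.48 ± 0.12 on the log2 scale. 3 members fell: BST2 (Cre16.g663400) (-1.26 ± 0.13), LCID (Cre04.g222800) (-2.14 ± 0.48) and CCP2 (Cre04.g222750) (-0.74 ± 0.19). With 5 up and 3 down of 17 (5 and 4 adjusted over the list alone), camera gave an adjusted p of 0.0669, which became 0.00913 without dnmt1 mt- replicate 2, 0.0486 and 0.0487 without dnmt1 mt+ replicate 1 or 2, and 0.0419 with replicate number as a block. Fry called the list higher (adjusted p = 0.0424), and with an estimated correlation camera gave an adjusted p of 0.639. LCID was no longer called without dnmt1 mt- replicate 1, BST3 without that library or WT mt- replicate 2, and CCP2 without WT mt- replicate 1 or either library of dnmt1 mt-.

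Of 17 photosystem and Rubisco genes, 9 were higher in the libraries labelled dnmt1 mt- and 8 were not called (12 higher adjusted over the list alone), with log2 fold changes of 0.42 ± 0.09 for PSBX (Cre02.g082750), 0.36 ± 0.08 for PSAN (Cre02.g082500), 0.31 ± 0.08 for PSBQ (Cre08.g372450) and 0.33 ± 0.09 for PSBP1 (Cre12.g550850). Of 24 antenna genes 11 rose, LHCB4 (Cre17.g720250) and LHCB5 (Cre16.g673650) among them (0.51 ± 0.11 and 0.39 ± 0.08), 4 fell and 9 were not called (16 higher and 4 lower adjusted over the list alone). Those that fell were LHCBM8 (Cre06.g284250) (-0.96 ± 0.13), LHCBM4 (Cre06.g283950) (-0.70 ± 0.11), LHCBM9 (Cre06.g284200) (-0.48 ± 0.14) and the photoprotection gene LHCSR1 (Cre08.g365900) (-1.95 ± 0.42). Camera gave adjusted p = 0.00106 for the photosystem list and 0.0226 for the antenna list, and with an estimated correlation an adjusted p of 0.639 for both. The antenna list no longer passed without WT mt- replicate 1 (adjusted p = 0.220). The calls of PSAN, PSBQ and PSBP1 were lost without WT mt- replicate 1 or either library of dnmt1 mt-, that of PSBX without WT mt- replicate 1 or dnmt1 mt- replicate 2, and that of LHCB4 without WT mt- replicate 1 or dnmt1 mt- replicate 1. LHCBM9 lost its call without any 1 of the 4 mt- libraries, and LHCSR1 without WT mt- replicate 2 or dnmt1 mt- replicate 1.

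**Figure D2:**
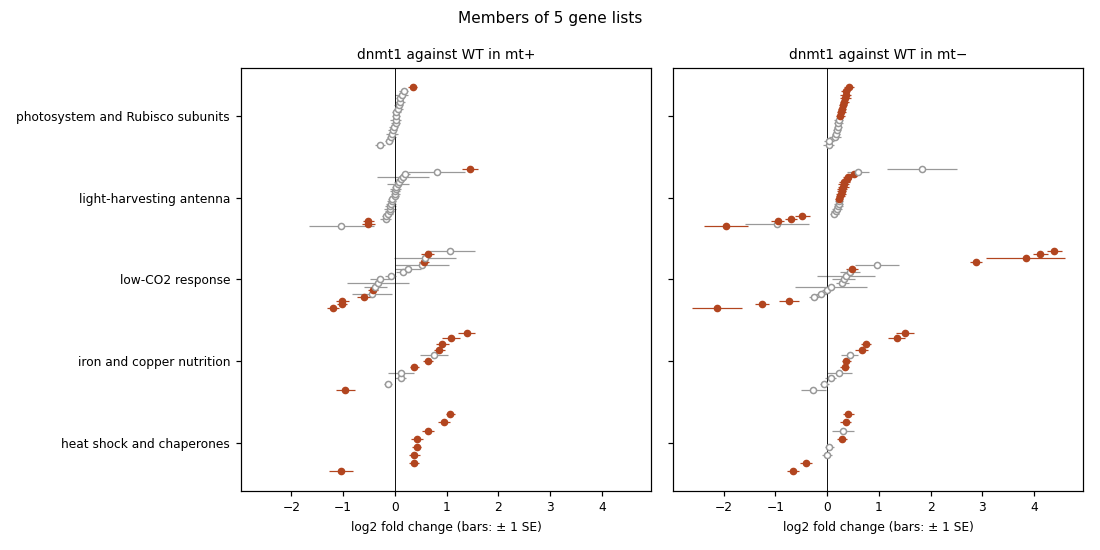
Log2 fold change of each tested member of 5 gene lists in libraries labelled dnmt1 against WT, in mt+ on the left and in mt- on the right, with bars of ± 1 standard error; filled points were called at an adjusted p under 0.05. In mt- the points at 4.39, 4.12, 3.83 and 2.88 in the low-CO2 row are CAH4, CAH5, LCIA and CAH1.

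Of 67 tested chloroplast-encoded genes, 26 were lower in the libraries labelled dnmt1 mt- and 41 were not called (27 lower adjusted over the list alone), with a median log2 fold change of -0.74 (camera adjusted p = 1.27e-06, and adjusted p = 0.639 with an estimated correlation). All chloroplast genes together took 0.0563% and 0.0659% of counts in WT mt- and 0.0395% and 0.0298% in the libraries labelled dnmt1 mt-, and their share also differed between the WT mt+ replicates (0.0660% and 0.0407%). The 67 tested genes had a median level of 4.53 CPM and an estimated correlation of 0.652, so the calls are not separate results. Whether transcript level or the amount of chloroplast RNA in a library changed was not tested. Of 8 mitochondrion-encoded genes 2 rose (4 adjusted over the list alone; camera adjusted p = 0.00735, and adjusted p = 0.639 with an estimated correlation). Of 11 iron and copper genes 6 rose (7 adjusted over the list alone): CYC6 (Cre16.g651050) by 1.51 ± 0.17, CTR2 (Cre10.g434350) by 1.34 ± 0.16, CTR1 (Cre13.g570600) by 0.75 ± 0.10 and FEA2 (Cre12.g546600) by 0.67 ± 0.13 on the log2 scale were those with the smallest p (camera adjusted p = 0.00524, and adjusted p = 0.639 with an estimated correlation). The heat shock list split, with 3 members higher, HSP70B (Cre06.g250100) (0.41 ± 0.10), CLPB3 (Cre02.g090850) (0.36 ± 0.10) and HSP90A (Cre09.g386750) (0.29 ± 0.09), and 2 lower, HSP22F (Cre14.g617400) (-0.66 ± 0.11) and HSP22E (Cre14.g617450) (-0.41 ± 0.11), 2 similar genes (camera adjusted p = 0.805). HSP70B, HSP90A and HSP22E lost their calls without any 1 of the 4 mt- libraries, HSP90A also without either library of dnmt1 mt+, with DESeq2 and with library size scaling, and CLPB3 with that scaling or without WT mt- replicate 2 or either library of dnmt1 mt-.

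Over all tested genes, 1820 were higher and 1774 lower in the libraries labelled dnmt1 mt-, of which 292 and 283 at least 2-fold. Scaling by library size alone called 1209 higher and 2442 lower, a share of higher calls of 33.1% against 50.6%. Cre06.g278278 again had 0 reads in WT and 20.5 ± 2.73 CPM in the libraries labelled dnmt1, at least 122-fold higher. Its place in the order of rises is not known. By the rule used in mt+ the largest rises from a level above 0 reads were of Cre06.g800688, from 0.358 ± 0.256 to 63.6 ± 4.67 CPM (log2 fold change 7.59 ± 0.22), and Cre05.g800547 (7.04 ± 0.25). In WT mt- Cre06.g800688 had 4 and 8 reads and Cre05.g800547 4 and 6, so the sizes of these fold changes are uncertain. The largest falls were of Cre17.g731571, from 41.4 ± 1.11 to 2.45 ± 0.770 CPM (-4.08 ± 0.17), and Cre17.g731591 (-3.26 ± 0.20). Without WT mt- replicate 1 or 2 the calls were 761 higher and 832 lower, and 969 higher and 883 lower; without dnmt1 mt- replicate 1 or 2 they were 846 higher and 845 lower, and 975 higher and 898 lower. They were 2832 higher and 2840 lower without WT mt+ replicate 1, 2921 higher and 2761 lower without WT mt+ replicate 2, and 2833 higher and 2826 lower in a fit to these 2 groups alone.

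Whether the effect differed between the mating types was tested directly. The carbonic anhydrase genes CAH4 (Cre05.g248400), CAH5 (Cre05.g248450) and CAH1 (Cre04.g223100) were lower in the libraries labelled dnmt1 in mt+ and higher in mt-, with differences of log2 fold changes (mt+ minus mt-) of -5.40 ± 0.19, -5.31 ± 0.18 and -3.90 ± 0.14 (edgeR, Benjamini-Hochberg adjusted p = 3.50e-11, 3.50e-11 and 8.36e-11). CYC6 (Cre16.g651050) also had opposite signs (-2.46 ± 0.25), as did LHCBM9 (Cre06.g284200; 1.93 ± 0.21), HSP22E (Cre14.g617450; 1.05 ± 0.16), HSP22F (Cre14.g617400; 1.08 ± 0.16) and the DMT1 locus Cre10.g461750 (-2.66 ± 0.17). HSP90A rose more in mt+ (0.78 ± 0.13). Of genes with no symbol, Cre13.g565250 (4.81 ± 0.39) and Cre17.g731571 (3.82 ± 0.21) had the largest positive differences at a mean of at least 5 CPM, and Cre02.g114350 (-4.09 ± 0.28) the largest negative one outside the carbonic anhydrases. CTR1 (0.11 ± 0.14), CTR2 (0.05 ± 0.23), FEA2 (0.24 ± 0.18) and FOX1 (0.27 ± 0.13) were not called for a difference, though FOX1, CTR2 and FEA2 were without WT mt+ replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.00150, 0.0411 and 0.0102). The 4 genes above have the IDs Cre13.g570600, Cre10.g434350, Cre12.g546600 and Cre09.g393150.

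In all, 2109 genes were called, 1040 with a higher and 1069 with a lower fold change in mt+. Of these, 389 were called in both mating types in opposite directions. Between the mating types, 707 of them were called in WT alone, 800 in the libraries labelled dnmt1 alone, 465 in both and 137 in neither. Library size scaling called 1250 higher and 690 lower (64.4% higher against 49.3%). The number called was 3158 and 4341 without WT mt+ replicate 1 and 2, 1088 and 1117 without WT mt- replicate 1 and 2, 1138 and 1131 without dnmt1 mt+ replicate 1 and 2, and 1163 and 1196 without dnmt1 mt- replicate 1 and 2.

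Averaged over both mating types, the copper and iron genes CTR2 (Cre10.g434350), CTR1 (Cre13.g570600), FEA2 (Cre12.g546600) and FOX1 (Cre09.g393150) were higher in the libraries labelled dnmt1, with log2 fold changes of 1.37 ± 0.11, 0.81 ± 0.07, 0.79 ± 0.09 and 0.51 ± 0.06. Their list had 6 members higher of 11 (camera adjusted p = 0.00220, and adjusted p = 0.617 with an estimated correlation). Chloroplast-encoded genes were lower for 18 and higher for 2 of 67, and photosystem and Rubisco genes higher for 4 of 17 (camera adjusted p = 0.00375 and 0.0183, and with an estimated correlation an adjusted p of 0.617 for both). Neither average shows an effect shared by the mating types. The chloroplast median was 0.14 in mt+ and -0.74 in mt-, and 1 photosystem and Rubisco gene was higher in mt+ against 9 in mt-. The chloroplast list no longer passed without WT mt+ replicate 1 (adjusted p = 0.252), nor the photosystem list without WT mt+ replicate 2 (0.113), WT mt- replicate 1 (0.145) or dnmt1 mt+ replicate 2 (0.0523). Newly past camera were the antenna, heat shock and mitochondrion lists without WT mt+ replicate 1 (adjusted p = 0.0362 for each) and the low-CO2 and mitochondrion lists without dnmt1 mt- replicate 2 (0.0494 for each). Cre06.g800688 and Cre05.g800549 rose by 8.12 ± 0.17 and 6.56 ± 0.13, and Cre01.g009101 and Cre04.g220850 had log2 fold changes of -2.46 ± 0.16 and -2.31 ± 0.11. The size of the rise of Cre06.g800688 is uncertain, as it had 2, 2, 4 and 8 reads in the WT libraries. The averaged effect was called for 1976 higher and 1957 lower genes. Across the separate comparisons, 395 genes were higher in both mating types and 447 lower in both, where independent lists would share 169 and 157. Another 270 were higher in mt+ and lower in mt-, and 119 the opposite, with 164 and 161 for independent lists. The 2 comparisons share no library, but their tests share 1 estimate of spread per gene. Genes that are easy to call can therefore be in both lists without a shared effect, and the numbers for independent lists do not allow for this. Spearman's correlation of the 2 log2 fold changes across genes was 0.18. An additive model called 890 higher and 993 lower, and library size scaling 1478 higher and 2485 lower (37.3% higher against 50.2%). Higher calls numbered 1250 without WT mt- replicate 1, and lower calls 1254, 1295 and 1296 without dnmt1 mt+ replicate 1, dnmt1 mt+ replicate 2 and dnmt1 mt- replicate 1.

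In WT, some genes within the ID range of the mating-type region followed the mating-type labels. FUS1 (Cre06.g252750), which encodes a fusion protein of mt+ gametes, had 8 and 18 reads in WT mt+ and 0 in both WT mt- libraries. Its mean in WT mt+ was 5.19-fold above a floor of 3 counts per library, which with so few reads is no firm bound. Cre06.g253051 was at 14.5 ± 3.05 CPM in WT mt+ and 0.179 ± 0.128 CPM in WT mt-. Cre06.g800595, with an ID outside the range, was at 0.494 ± 0.219 CPM in WT mt+ and 242 ± 19.4 CPM in WT mt- (log2 fold change -8.84 ± 0.17). Cre06.g800600 and Cre06.g800601 had 0 reads in both WT mt+ libraries and were at least 203-fold and 106-fold higher in WT mt-. Their IDs lie outside that range, and their place relative to the region is not shown by the tables used here. Also outside the range, CAH4 (Cre05.g248400), CAH5 (Cre05.g248450) and CAH1 (Cre04.g223100) were higher in WT mt+ than in WT mt- by log2 fold changes of 4.34 ± 0.14, 4.14 ± 0.14 and 3.60 ± 0.11, and CYC6 (Cre16.g651050) by 1.27 ± 0.18, while HSP70B (Cre06.g250100) and LHCBM9 (Cre06.g284200) were lower (-1.27 ± 0.11 and -2.02 ± 0.15).

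In WT, 1615 genes were higher and 1665 lower in mt+. Photosystem and Rubisco genes were higher in mt+ for 8 of 17 and antenna genes for 7 of 24, with 2 antenna genes lower (camera adjusted p = 7.57e-04 and 0.0144, and with an estimated correlation an adjusted p of 0.851 for both). Of 8 mitochondrion-encoded genes 1 was higher (camera adjusted p = 0.0166, and adjusted p = 0.851 with an estimated correlation), a call lost without WT mt+ replicate 1 (adjusted p = 0.196) or WT mt- replicate 1 (adjusted p = 0.0775). The antenna list no longer passed without WT mt+ replicate 1 (adjusted p = 0.113) or without WT mt- replicate 1 (adjusted p = 0.143). Newly past camera were the chloroplast list without WT mt+ replicate 1 (median -0.51, adjusted p = 4.47e-05) or WT mt- replicate 1 (median -0.20, adjusted p = 0.0367). So was the heat shock list without WT mt+ replicate 1 (median -0.20, adjusted p = 0.0493). Library size scaling called 1203 higher and 1970 lower (37.9% higher against 49.2%). Calls numbered 566 higher and 740 lower without WT mt- replicate 1, 664 higher and 806 lower without its replicate 2, 2499 higher and 2370 lower without WT mt+ replicate 2, and 791 higher and 980 lower in a fit to these 2 groups alone.

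The same genes of the region also differed between the mating types in the libraries labelled dnmt1. FUS1 (Cre06.g252750) had 18 and 28 reads in the libraries labelled dnmt1 mt+ and 0 in those labelled dnmt1 mt-. Its mean was 7.48-fold above a floor of 3 counts per library, again no firm bound. Cre06.g253051 was higher in mt+ (6.18 ± 0.37). Cre06.g252743 differed by at least 41.8-fold, with 0 reads in both libraries of the lower group. Cre06.g800600 and Cre06.g800601, outside the range, were at least 134-fold and 114-fold higher in mt-. Cre06.g800595 was again lower in mt+ (-8.81 ± 0.16). CAH4 (Cre05.g248400) and CAH5 (Cre05.g248450), higher in mt+ in WT, were lower in mt+ in the libraries labelled dnmt1 (-1.06 ± 0.12 and -1.17 ± 0.12), as was CYC6 (-1.19 ± 0.17), while HSP90A (Cre09.g386750) was higher (0.88 ± 0.09) and HSP70B (Cre06.g250100) lower (-0.74 ± 0.11), as in WT. The DMT1 locus Cre10.g461750 was lower in mt+ (-2.58 ± 0.12), and Cre17.g731571 higher (3.94 ± 0.17).

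Chloroplast-encoded genes were higher in dnmt1 mt+ than in dnmt1 mt- for 16 of 67 (camera adjusted p = 3.34e-06, and adjusted p = 0.860 with an estimated correlation). In all, 1628 genes were higher and 1735 lower in mt+. Of the genes called in WT, 340 were higher and 486 lower in mt+ in both genotypes, against 172 and 189 for independent lists. Another 267 were lower in mt+ within WT and higher in mt+ within the libraries labelled dnmt1, and 129 the opposite, against 178 and 184. Here too the tests share the estimate of spread per gene, which the numbers for independent lists do not allow for. Leaving out dnmt1 mt+ replicate 1 or 2, or dnmt1 mt- replicate 1 or 2, gave 1549, 1452, 1542 and 1574 calls, and leaving out WT mt+ replicate 1 or 2 5245 and 5320. Calls numbered 2589 higher and 2632 lower in a fit to the groups labelled dnmt1 alone, and 1133 genes were lower under the stricter filter.

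The mating-type region was also examined as a block of 70 tested genes with neighbouring ID numbers, FUS1 among them. Between the mating types, 15 of them were higher and 16 lower in mt+ in WT, and 16 and 25 in the libraries labelled dnmt1. By genotype, 5 were higher and 9 lower in the libraries labelled dnmt1 in mt+, and 7 and 7 in mt-. Camera gave the block an adjusted p of 0.413 and 0.885, with an estimated correlation 0.654 and 0.860. Fry called it lower in mt+ (adjusted p = 0.0130) and not in mt- (0.424). FUS1 was not called for genotype in mt+ (log2 fold change 0.71 ± 0.55, edgeR, Benjamini-Hochberg adjusted p = 0.419); at 0.871 ± 0.270 and 1.48 ± 0.569 CPM a small change was not detectable at this depth. In WT the block's median and mean log2 difference between mating types had opposite signs (-0.03 and 0.33), since a few genes differed by much.

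**Figure D3:**
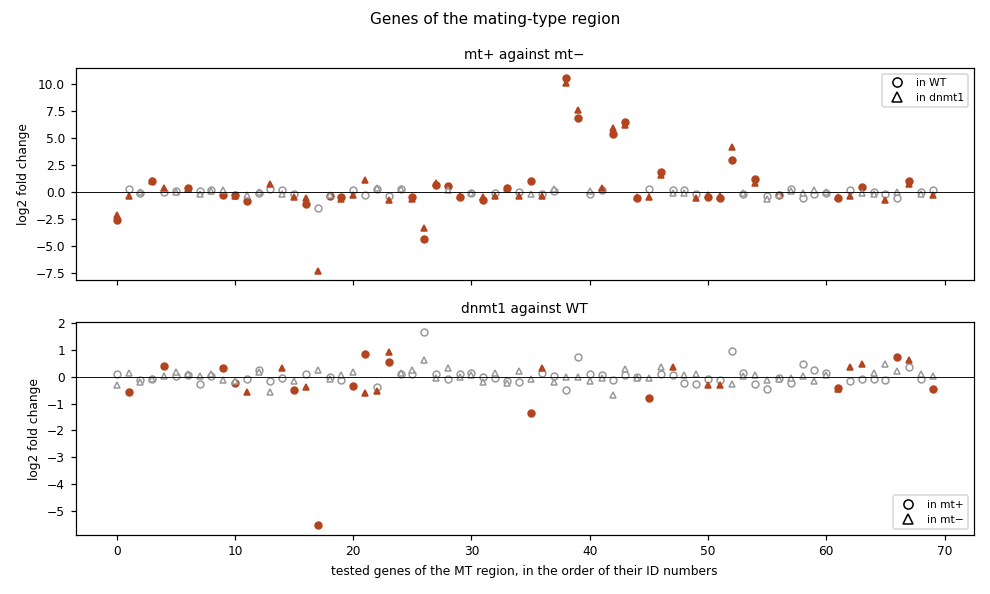
Log2 fold change of the 70 tested genes of the mating-type region in the order of their ID numbers, between mating types in the upper panel and between genotypes in the lower one; filled points were called at an adjusted p under 0.05, and genes with 0 reads in a group are drawn at fitted values, which are no bounds. Cre06.g253051 lies at 6.41 in WT and 6.18 in the libraries labelled dnmt1 in the upper panel.

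Called genes were next to each other more often than random placement gave. In mt+, 12% of genes called for genotype had a following tested gene called in the same direction, against a mean of 9.25% and a highest value of 10.8% in 1000 random placements. In mt- the share was 14.9% against a mean of 12% and a highest value of 13.6%, and between mating types it was 14.0% in WT and 14.5% in the libraries labelled dnmt1 (permutation p = 0.000999 for each of the 4, the smallest that 1000 placements can give). Overlapping neighbours can share reads where strand is not used, and the strand setting of the counting is not given in the sources used here. None of the 17 chromosomes stood apart as a whole by camera (smallest adjusted p = 0.986 in mt+ and 0.635 in mt-). Medians of the log2 fold change ran from -0.10 to 0.01 in mt+ and from -0.12 to 0.05 in mt-. Fry called chromosomes 6, 3, 10 and 12 higher in mt+ (adjusted p = 0.0203, 0.0326, 0.0326 and 0.0383) and none in mt-. Of the nitrogen assimilation list, 2 of 8 genes were tested, NII1 (Cre09.g410750), with log2 fold changes of -1.36 ± 0.84 in mt+ and -0.82 ± 0.67 in mt-, and NIT2 (Cre03.g177700), with -0.12 ± 0.11 and 0.03 ± 0.11; neither was called in any comparison.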

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

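The test of the other low-CO2 genes was chosen after the carbonic anhydrase values had been seen. The fold change between the libraries labelled dnmt1 and WT in mt+ differed from that in mt- by a test of the difference itself for 2109 genes. Among the 52 genes the text names in the genotype comparisons, it differed for 26, of which 10 were called in both mating types in opposite directions. Some of these genes were named because they ranked high for this difference. Values below are the log2 fold change in mt+ minus that in mt-, under the labels as given.

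Of 12 positive differences, the photoprotection gene LHCSR1 (Cre08.g365900) had 2.76, the low-CO2 gene LCID (Cre04.g222800) 2.65, LHCBM9 (Cre06.g284200) 1.93 and BST2 (Cre16.g663400) 1.42. The chaperone genes HSP22F (Cre14.g617400), HSP22E (Cre14.g617450), HSP90A (Cre09.g386750) and HSP70B (Cre06.g250100) had 1.08, 1.05, 0.78 and 0.54, and CAH3 (Cre09.g415700) had 0.57. Cre13.g565250, Cre17.g731571 and Cre17.g731591 had 4.81, 3.82 and 2.66.

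Of 14 negative differences, those of photosynthesis genes were -0.40 for PSBP1 (Cre12.g550850), -0.44 for LHCB5 (Cre16.g673650) and -0.60 for LHCB4 (Cre17.g720250). EPYC1 (Cre10.g436550) had -0.89, HSP22A (Cre07.g318800) -1.35, CYC6 (Cre16.g651050) -2.46 and the DMT1 locus (Cre10.g461750) -2.66. CAH1 (Cre04.g223100), LCIA (Cre06.g309000), CAH5 (Cre05.g248450) and CAH4 (Cre05.g248400) had -3.90, -4.17, -5.31 and -5.40. Cre01.g009101, Cre16.g686285 and Cre02.g114350 had -1.62, -1.63 and -4.09.

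By camera, 5 lists differed: chloroplast-encoded genes (adjusted p = 5.02e-06, 10 of 67 genes with a higher fold change in mt+), photosystem and Rubisco genes (adjusted p = 0.00932, 0 higher and 1 lower of 17), heat shock genes (adjusted p = 0.00932, 4 higher and 1 lower of 8), mitochondrion-encoded genes (adjusted p = 0.00932, 0 higher and 1 lower of 8) and antenna genes (adjusted p = 0.0360, 2 higher and 5 lower of 24). With an estimated correlation the adjusted p was 0.600 for chloroplast, 0.600 for photosystem, 0.491 for heat shock, 0.491 for mitochondrion-encoded and 0.600 for antenna genes. Without WT mt+ replicate 1 the photosystem, mitochondrion and antenna lists no longer passed (adjusted p = 0.0775, 0.0728 and 0.198), nor did the photosystem and antenna lists without WT mt- replicate 1 (0.154 and 0.215). The antenna list was also lost without dnmt1 mt+ replicate 1 (0.0672), dnmt1 mt- replicate 1 (0.0552) or dnmt1 mt- replicate 2 (0.0533). The low-CO2 list newly passed without WT mt+ replicate 2 (0.0414) or dnmt1 mt+ replicate 1 (0.0430).

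The carbonic anhydrase genes CAH1, CAH4 and CAH5 were lowest in WT mt-. A single aberrant WT mt- library was argued against, since the lowest log2 fold change of CAH4 (Cre05.g248400) in mt- was 4.31 with either WT mt- library left out. A low-CO2 response of the other cultures stays open. Of 14 other tested low-CO2 genes, 3 were called lower in the libraries labelled dnmt1 mt- than in WT mt-, but only 1, BST2 (Cre16.g663400), whichever library was left out; 2 were called higher and the median log2 fold change was 0.18. A difference of the WT mt- cultures in aeration or growth stage that acts on the carbonic anhydrase genes more than on the rest, a difference between the CC-5325 strains other than the mutation, and an effect of the mutation itself stay open, since each would separate the same libraries.

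The number of genes whose effect differed between mating types could come from a single aberrant WT mt+ library, since that pair stood farthest apart. Without either WT mt+ library at least 3158 genes were called for the difference, against 2109 with all 8 libraries. That count decides nothing, since without WT mt+ replicate 1 or 2 calls also rose for genotype in mt-, which does not use that group (5672 and 5682 against 3594): the spread of this pair then leaves the fit, so an aberrant library stays open. Strain differences between the mt+ and mt- lines, and lines labelled dnmt1 of a different making in each, stay open, as the labels give 1 strain background per mating type. Batch was not tested, as no label gives one.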

How the results depend on the processing

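The off and on limits and the halved counts were chosen after the data were seen; the other alternatives were fixed earlier. Over 161 gene and list results and 2241 alternative values, 2141 kept direction and side of the threshold, 81 no longer passed, 18 newly passed and 1 turned: chloroplast-encoded genes in mt+, with a median of -0.40 without WT mt+ replicate 2 (and 0.62 without replicate 1). Many of the alternative values leave out a library of a group that was not compared. Many of the genes were also named for a large fold change or a small p. Part of the agreement was thus built in, and its share is no measure of stability. The DMT1 locus kept its calls throughout.

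A 2-fold minimum, stricter by construction, left 410 higher and 154 lower in mt+, 292 higher and 283 lower in mt-, 592 higher and 239 lower for the difference, 194 higher and 97 lower for the mean, and 185 higher and 285 lower and 395 higher and 207 lower between mating types in WT and dnmt1. Fits to the 2 compared groups called 814 higher and 705 lower in mt+, 2833 higher and 2826 lower in mt-, 791 higher and 980 lower in WT and 2589 higher and 2632 lower in dnmt1. Fits that held WT mt+ thus called fewer genes than the main fit, and those without it more. The WT mt+ pair stood farthest apart (SD of log2 differences 0.47), and its spread enters only the fits that hold it. Library size scaling called 1209 higher in mt- and 690 lower for the difference. It leaves out the TMM factors, which were 1.07 and 1.01 in WT mt- and 0.975 and 0.968 in dnmt1 mt-. The median log2 fold change in mt- thereby moved from 0.00746 to -0.0897. The additive model called 890 higher and 993 lower for the mean; the cause was not tested. At a mean of at least 10 CPM, with fewer genes tested, 1133 were lower in mt+ in dnmt1. DESeq2, RLE factors, no filter and halved counts kept each count of called genes within 1.5 times. With an estimated correlation 0 of 8 lists passed in each of the 6 comparisons (the estimates of the 7 lists other than the mating-type region were 0.334 to 0.654, above the preset 0.01). Fry called the heat shock, iron and copper and mating-type region lists in mt+, iron and copper and heat shock for the mean, photosystem, low-CO2, heat shock and mating-type region in WT and mating-type region in dnmt1. It called 1 in mt-, the low-CO2 list, and 3 for the difference, the low-CO2, heat shock and mating-type region lists; the cause was not tested.

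Leaving out 1 library gave, as lowest and highest counts of higher and of lower genes, 771 to 2018 and 529 to 2195 in mt+, 761 to 2921 and 832 to 2840 in mt-, 624 to 1993 and 453 to 2348 for the difference, 1250 to 2905 and 1254 to 2680 for the mean, 566 to 2499 and 740 to 2370 in WT, and 779 to 2620 and 673 to 2780 in dnmt1. Lists past camera ranged from 1 to 3 in mt+, 4 to 6 in mt-, 2 to 6 for the difference, 2 to 5 for the mean and 2 to 3 in WT, and stayed at 1 in dnmt1.

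With replicate number as a block the calls were 1526 higher and 1499 lower in mt+, 1969 higher and 1926 lower in mt-, 1159 higher and 1200 lower for the difference, 2110 higher and 2092 lower for the mean, 1775 higher and 1822 lower in WT and 1743 higher and 1877 lower in dnmt1, and the low-CO2 list passed in mt- (adjusted p = 0.0419). Deviations of equally numbered replicates correlated across genes by -0.0482 to 0.149 over 6 pairs of groups, so the numbers are not shown to mark a batch.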

Other observations

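The tests of the chromosome segment and of the ID numbers, and the off and on limits, were chosen after the genes below had been seen. A set of 13 genes had at most 0.3 CPM in each of the 4 WT libraries and at least 1 CPM in each of the 4 libraries labelled dnmt1, and no gene had the opposite pattern. Cre06.g278278, with no read in WT, was at 18.4 ± 2.89 CPM (SD, n = 4) in those libraries. Cre17.g802133 and Cre03.g198500 each had 4 reads over the WT libraries and were at 9.68 ± 0.810 and 8.32 ± 0.970 CPM. In all, 6 of the genes had no read in any WT library. IDs whose number begins with 8, which are missing from the older gene set, made up 8 of the 13 (61.5%) against 818 of 13961 genes at 1 CPM or more in all libraries labelled dnmt1 (5.86%, Fisher's exact test, 2-sided, p = 1.33e-07). The background was not matched for level, and the test takes the genes as independent. Cre17.g802127, Cre17.g802130 and Cre17.g802133 have close ID numbers and may not be independent. An off limit of 0.1 CPM left 7 genes, and an on limit of 2 CPM 6. Leaving out 1 library gave 13 to 15, but that step only removes a condition and could not lower the count. It therefore does not show whether the set depends on a single library.

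Technical explanations of this set were weighed. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many such genes, the real one, with 13, and the highest other, by mating type, gave 4 (7 counted in either direction). Splits that part a replicate pair gave 0, which the pairs' likeness sets, so that 3 splits bear on chance, too few for a share under 0.05. Thinning every library to the smallest total left 11 of the genes. That count decides little, since the limits are in CPM, which thinning hardly changes. Library totals were 12204374 and 16420519 counts in WT mt+ and 21115955 and 14722049 in WT mt-. In the libraries labelled dnmt1 they were 16712723 and 15091414 in mt+ and 16136054 and 15176221 in mt-. WT mt+ replicate 1 and WT mt- replicate 2 were thus the shallowest. The WT libraries were not shallower throughout, as WT mt- replicate 1 was the deepest library. That the genes were off in that library was required by the limits that picked them, so it is no separate evidence about depth. A single chromosome segment behind the whole set was argued against, since the IDs lie on 11 chromosomes or scaffolds. Part of the set may still share a segment, as Cre17.g802127, Cre17.g802130 and Cre17.g802133 have close ID numbers. Other differences between the lines labelled dnmt1 and WT, and an effect of the mutation itself, were not tested and stay open.

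For the mean effect over both mating types, with mating type as a term, 34 of the 35 splits could be fitted, and 1 of them, the real one, called as many as 1883 genes. The highest other split, WT mt+ with dnmt1 mt- against the rest, called 367. Splits that part a replicate pair called 0, so 2 splits bear on chance, too few for a share under 0.05.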
